A study of Arabidopsis thaliana with 12 samples.

How the data were processed

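Polyadenylated RNA of 10-day-old Arabidopsis thaliana seedlings (ecotype Columbia) was profiled in 4 conditions with 3 libraries each, 12 libraries in all. The seedlings carried the tfIIs-1 insertion in the gene of the transcript elongation factor TFIIS, and an estradiol-inducible transgene for either GFP-tagged TFIIS (GFP-TFIIS) or a GFP-tagged mutated form (GFP-TFIISmut). Each line received 2 mM estradiol, the concentration as the labels give it, or ethanol (mock) for 24 h. RNA was extracted with an RNeasy kit and made into stranded mRNA libraries with an Illumina TruSeq kit, per the labels' protocols.

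The deposited table holds a single value per gene and condition, so the authors combined the 3 libraries of a group before depositing it; how they did so is not given in the sources used here. The deposited values were read as FPKM, fragments scaled to transcript length and library size by the authors before deposition. No header or label names that unit for the deposited values: it was inferred from the table's layout, from column sums that differ between conditions, and from the decimals. Bowtie2 2.3.5 is named per the submitters' processing notes; the quantification tool, the genome build and the annotation are not given in the sources used here. Which column belongs to which line and treatment is inferred: the 4 column names are abbreviations that no label spells out, and they were read as the construct crossed with 0 or 24 h of estradiol, the name with an added M as GFP-TFIISmut. Every value given for a line rests on this reading. Reads per library are unknown, so no interval or detection floor was computed.

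The design written before the data were examined assumed values per library, with a test across 12 libraries. With pooled values no test, standard error, replicate block or left-out library was possible, and the unit differed from the one hoped for. Differences were therefore described by a rule of size: a gene counted as higher or lower when its log2(FPKM + 1) values differed by at least 1, which is called 2-fold here, and the larger FPKM was at least 5. A difference on this scale understates that of genes with low FPKM. The mock pools of the lines were compared in the same way, as a measure of how far pools differ without induction.

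The table has 32705 rows. The 38 rows that share 19 repeated identifiers were left out, which left 32667. A gene listed at 0 in a compared pool was left out of that comparison, since such a 0 can be a failed estimate: RBCS-1A and LHCB1.3, which encode abundant photosynthesis proteins, are listed at 0 in both mock pools. In 754 rows several neighbouring genes share a value, and 218 rows are organelle genes. Of all rows, 32045 identifiers matched the TAIR10.1 reference annotation. Coordinates given below are those of TAIR10.1, because the loci in the table are merged intervals: 38.0% of matched rows have the same start and 37.3% the same end.

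Gene lists were fixed before the data were examined: 20 lists of processes and 4 of tissue markers, with 389 genes. Of these, 383 were in the table, and 2 were dropped because the reference gives their symbol to another locus, which left 381. A list member counted as measured when it reached 1 FPKM in a compared pool and was not at 0 in either. Each list's median difference was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins; a list outside their central 95% is called above or below. About 1.2 of 24 lists of independent genes would lie outside by chance. The comparison with random lists describes the pools and is no test across seedlings, and co-regulated members make a list leave the interval more easily. Between the mock pools, neither of them induced, 5 lists lay above and 9 below. Lying outside thus does not by itself show an effect of induction.

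The rule for named genes, also fixed beforehand, takes TFIIS, the 10 largest and 10 smallest differences of each induced against mock comparison, the 5 largest and 5 smallest of the other comparisons, and up to 4 members per list. Its criteria on separate libraries and on p-values could not be applied, so list members were taken by the size of their difference. Fewer genes are named than the rule allows.

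The bounds on what a single library could do rest on the pooled value being a plain mean. The bound for photosynthesis genes was first read as ruling a single library out; it is left open below because the way of pooling is not stated.

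The steps were tested on simulated data first. For TFIISmut induced against TFIISmut mock, 13856 genes were in the step, with noise set from the mock pools. Of genes given a 3-fold difference, 50 of 50 passed the rule. At 6-fold 49 of 50 passed, at 12-fold 49 of 50 and at 1.5-fold 0 of 50. Of unchanged genes, 0 of 13658 passed. The noise had the same normal spread for every gene, from the robust SD, so large differences between pools were not simulated. Between the real mock pools 146 of 14113 eligible genes passed, so the simulation gives no rate of false calls. Of 200 random lists without an effect, 10 lay outside the central 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives tried were quantile normalization, scaling to a common median, no filter, a pseudocount of 0.1, leaving out organelle genes or the 20 most abundant genes with the rest rescaled, and, chosen after the data were seen, nuclear protein-coding genes only, rows of a single gene only, a 4-fold rule, a minimum of 1 FPKM, organelle or the 20 most abundant genes left out without rescaling, and the other line's mock pool as control.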

Results

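Seedlings that lack intact TFIIS, a protein that helps RNA polymerase II resume after it has stalled, were induced to express either GFP-TFIIS or GFP-TFIISmut, and mRNA levels were set against those of uninduced seedlings. Each of the 4 conditions, with 3 libraries, is represented by the authors' single pooled FPKM value per gene, so no value below has an error or a number of replicates. Differences are given in size only and were not tested against the spread between seedlings. The pools hold 13683 to 13951 genes at 5 FPKM or more, and their FPKM sum to 903971 in TFIIS mock, 1030085 in TFIIS induced, 968488 in TFIISmut mock and 1058563 in TFIISmut induced. The 20 most abundant genes take 12.4%, 22.8%, 15.1% and 17.2% of these sums.

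TFIIS (AT2G38560; chromosome 2, 16134543 to 16136695) was examined first, because it is the induced gene. Its level was 21.1 FPKM in TFIIS mock and 742 FPKM in TFIIS induced, 35.2-fold higher. In the TFIISmut line it was 17.6 FPKM in mock and 87.0 FPKM after induction, 4.95-fold higher. The induced level was thus lower in the TFIISmut line, by a log2 difference of -3.08. Reads of the transgene and of the disrupted native gene share this row.

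**Figure D1:**
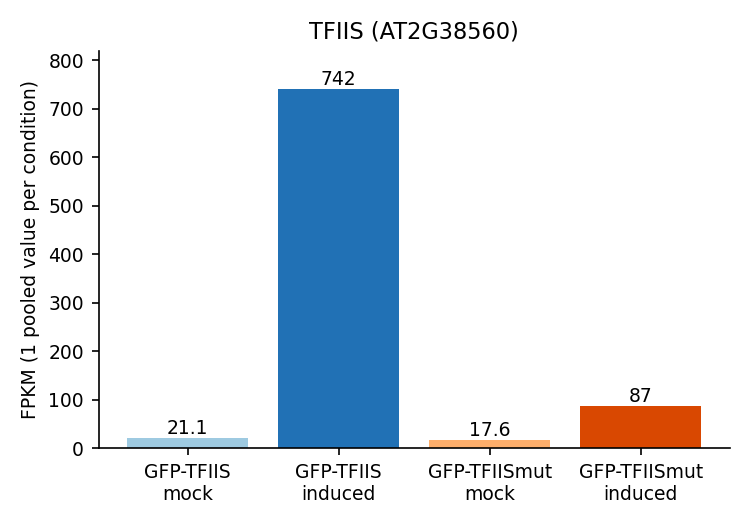
FPKM of TFIIS in the 4 pools, 1 pooled value per condition and no error bars. The induced pools stand at 742 FPKM (GFP-TFIIS) and 87.0 FPKM (GFP-TFIISmut), above mock pools at 21.1 and 17.6 FPKM.

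For TFIISmut induced against TFIISmut mock, which asks what expression of the mutated protein does to the transcriptome, genes of the salicylic acid response were higher as a group, with a list median of 2.08. PR1 (AT2G14610), a marker of the salicylic acid response, was at 2.41 FPKM in mock and 212 FPKM after induction, a log2 difference of 5.96. EGC2 (AT2G18660; chromosome 2, 8089411 to 8091736), which encodes a secreted natriuretic peptide-like protein, was at 1.39 and 187 FPKM, a log2 difference of 6.30. Photosynthesis genes were lower as a group, with all 24 measured members below 0 and a median log2 difference of -0.83. In all, 796 genes were 2-fold or more higher and 244 lower among 14456 eligible genes; with the TFIIS mock pool as control, 692 were higher and 350 lower, of which 587 and 141 were shared.

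The other genes with the largest differences include 2 enzymes of camalexin synthesis, an antimicrobial indole compound: CYP71A13 at 0.737 and 54.4 FPKM, and CYP71B15 (PAD3) at 3.89 and 116 FPKM. DTXL2, a transporter of the detoxification family, was at 0.970 and 105 FPKM, the flotillin gene FLOT2 at 1.29 and 61.4 FPKM, and the defensin gene PDF1.1 at 0.680 and 37.5 FPKM. AT3G60420 was at 3.40 and 136 FPKM, AT3G58150 at 2.62 and 86.4 FPKM, and AT1G57630 at 3.45 and 103 FPKM. Among the genes with the lowest differences were AT4G26530 (FBA5), a fructose-bisphosphate aldolase, at 125 and 25.5 FPKM, and BT1, a BTB and TAZ domain protein, at 78.1 and 16.1 FPKM. The cytochrome P450 gene CYP81D11 was at 82.9 and 17.9 FPKM, the glutaredoxin gene GRXS8 at 13.5 and 2.41 FPKM, the receptor-like kinase gene CRK30 at 6.35 and 0.765 FPKM, and AT5G25840 at 20.4 and 3.16 FPKM.

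Of the 19 measured genes of salicylic acid and defence, 19 lay above 0 and 16 were 2-fold or more higher, with a median of 2.08 against -0.17 to 0.21 for random lists. ICS1, the isochorismate synthase of salicylic acid synthesis, was at 8.33 and 42.3 FPKM, EDS1, a regulator of immune signalling, at 8.85 and 47.4 FPKM, and the transcription factor gene WRKY70 at 13.4 and 140 FPKM. The list of ethylene and early stress regulators had a median of 1.21, with 7 of 14 members 2-fold higher, among them TCH3 (AT2G41100), a calmodulin-like protein, at 100 and 885 FPKM, and WRKY40 at 15.1 and 60.9 FPKM. Oxidative stress and detoxification genes had a median of 0.81, with 8 of 17 members higher: UPOX was at 29.9 and 381 FPKM, AOX1A, the alternative oxidase of mitochondria, at 47.8 and 199 FPKM, and the glutathione transferase gene GSTU4 at 15.4 and 136 FPKM. Heat shock chaperones had a median of 0.82, with 6 of 17 members higher, including HSP90.1 at 9.57 and 29.0 FPKM and HSP23.6 at 0.290 and 6.26 FPKM.

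Senescence and chlorophyll breakdown genes had a median of 0.75, with 3 of 12 members higher and 1 lower: SAG13 was at 0.975 and 40.9 FPKM, and SEN1 (AT4G35770) at 105 and 37.8 FPKM. Proteasome genes had a median of 0.44, with 1 of 12 members 2-fold higher, the transcription factor gene NAC53 at 9.42 and 21.3 FPKM. Genes of the unfolded protein response had a median of 0.39, with 1 of 15 higher, BZIP60 at 28.2 and 81.8 FPKM. The DNA damage list had a median of 0.37, with 3 of 18 higher: ANAC044, a transcription factor, at 6.66 and 29.0 FPKM, and the cyclin-dependent kinase inhibitor genes SMR5, at 0.956 and 7.90 FPKM, and SMR7, at 3.59 and 14.2 FPKM. These 3 are regulators and not repair enzymes.

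Among the lower photosynthesis genes, PSAN was at 1812 and 823 FPKM, LHCA1 at 2246 and 1080 FPKM and RBCS1B at 1237 and 602 FPKM; these 3 passed the 2-fold rule. Auxin response genes had a median of -0.37, and HAT2 was at 23.4 and 12.5 FPKM; this list was also below in the TFIIS line, at -0.17, and lay within the range of random lists between the induced pools, at -0.11, so no response particular to the TFIISmut line is shown. Circadian clock genes had a median of -0.31, with LHY higher, at 1.32 and 7.53 FPKM. The tissue markers that lay below were those of root at -0.51, with CASP1 of the endodermis at 21.3 and 11.4 FPKM, of phloem and xylem at -0.42, with the sucrose transporter gene SUC2 at a log2 difference of -0.78, and of epidermis and stomata at -0.30. The epidermis list lay within the range of random lists when the TFIIS mock pool was the control, at -0.25, and between the induced pools, at -0.22. The 10 remaining lists lay within the central 95% of random lists. Their medians were 0.11 for jasmonate response, 0.00 for abscisic acid, drought and cold, 0.12 for cytosolic ribosomal proteins, 0.15 for ribosome biogenesis and 0.02 for cell cycle and replication. They were 0.13 for transcript elongation machinery, 0.06 for flowering time and seed dormancy, -0.06 for anthocyanin and flavonoids, 0.03 for glucosinolate synthesis and 0.24 for meristem markers. With the TFIIS mock pool as control, 4 of these 10 lay outside: abscisic acid at -1.68, anthocyanin at -0.37 and glucosinolate synthesis at -0.20 below, and elongation machinery at 0.29 above. With organelle genes left out and the pools rescaled to a common sum, 652 genes were higher and 350 lower, 65.1% higher against 76.5%; without the rescaling the counts were 792 and 241.

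**Figure D2:**
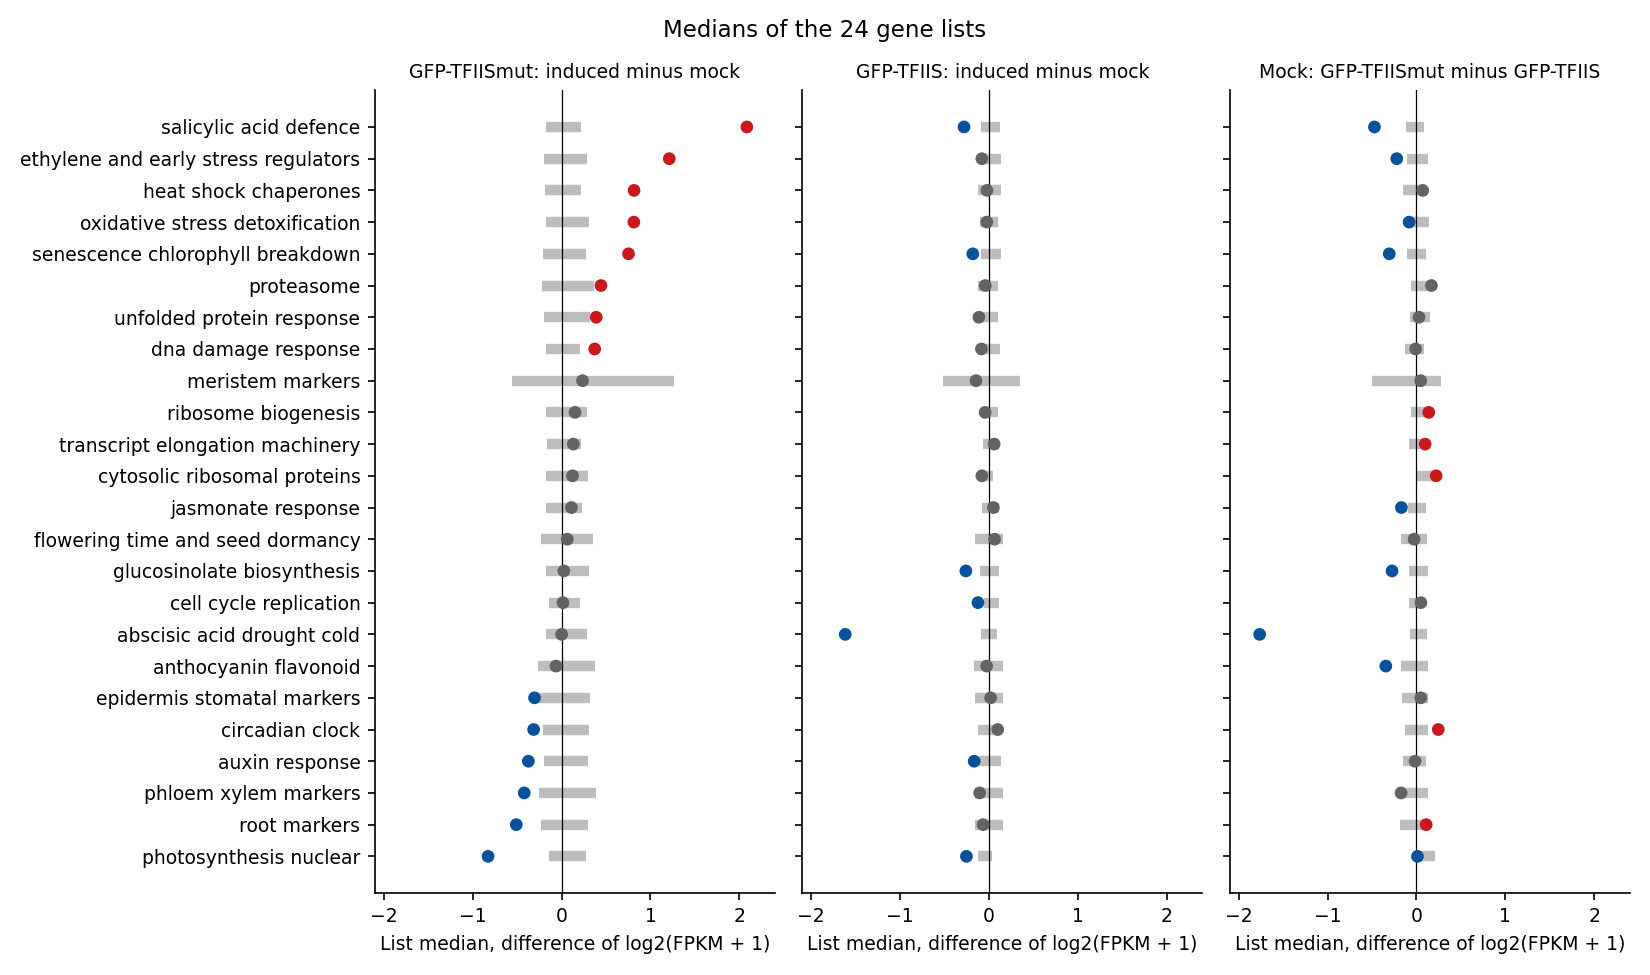
Median difference of log2(FPKM + 1) of the 24 gene lists (points) for induction in each line and for the mock pools, with the central 95% of 10000 random lists matched on level (grey bars). Red and blue points lie above and below that range. Salicylic acid and defence genes lie at 2.08 in the TFIISmut line, and abscisic acid genes at -1.62 in the TFIIS line and -1.76 between the mock pools.

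For TFIIS induced against TFIIS mock, the line with the unmutated protein had received the same estradiol treatment. In this comparison, 98 genes were 2-fold or more higher and 112 lower among 14203 eligible genes. Chloroplast transcripts were among the highest: 38 of 40 eligible organelle rows were 2-fold or more higher, with a median log2 difference of 3.04. A row is eligible when its larger FPKM is at least 5, so rows reaching it only after induction enter and can raise this share. Between the mock pools, 28 organelle rows were eligible. PSBA, which encodes the D1 protein of photosystem II, was at 25.3 FPKM in mock and 656 FPKM after induction, and organelle rows took 0.125% and 1.06% of all FPKM. The lowest genes respond to abscisic acid and water loss, led by the dehydrin gene RAB18 (AT5G66400; chromosome 5, 26518277 to 26519447) at 119 and 2.39 FPKM. Among nuclear protein-coding genes alone, 45 were higher and 103 lower.

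Of 20 measured genes of abscisic acid, drought and cold, 20 lay below 0 and 15 were 2-fold or more lower, with a median of -1.62. COR15A, a cold-regulated chloroplast protein, was at 560 and 59.1 FPKM, RD29A at 115 and 19.1 FPKM, and P5CS1, an enzyme of proline synthesis, at 113 and 22.7 FPKM. In the TFIISmut mock pool, RAB18 was at 1.78 FPKM, COR15A at 30.8 FPKM, RD29A at 12.2 FPKM and P5CS1 at 22.7 FPKM, so the TFIIS mock pool stood apart from the other pools. With the TFIISmut mock pool as control, the list median was 0.18, and 89 genes were higher and 36 lower. Of these, 59 of the higher and 12 of the lower genes passed the rule against each mock pool. Only 15 of the 59 and 10 of the 12 were nuclear protein-coding genes. LTP4, a lipid transfer protein gene, was at 49.6 and 1.76 FPKM, LTI65 (RD29B) at 18.8 and 0.519 FPKM, PXG3 (RD20) at 52.9 and 3.13 FPKM, SWEET15 at 15.3 and 0.446 FPKM, TSPO at 13.0 and 0.231 FPKM, and the late embryogenesis abundant gene LEA4-5 at 20.7 and 1.08 FPKM.

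A further 6 lists lay below in this comparison. Photosynthesis genes had a median of -0.25 with 25 of 25 members below 0, and cell cycle and replication genes -0.12; against the TFIISmut mock pool these medians were -0.25 and -0.24. Salicylic acid and defence genes had a median of -0.28, with PR1 at 8.44 and 2.89 FPKM, and the median was 0.19 against the TFIISmut mock pool. Glucosinolate synthesis genes had a median of -0.26, senescence genes -0.18 and auxin response genes -0.17; against the TFIISmut mock pool these 3 lists lay within the range of random lists, at -0.05, 0.13 and -0.05. Of the senescence genes, SWEET15 and the receptor-like kinase gene SIRK (22.5 and 9.14 FPKM) were 2-fold or more lower, and SEN1 (AT4G35770) was higher, at 52.2 and 130 FPKM. No list lay above, and the other 17 lay within the range of random lists. Of these, the unfolded protein response list lay at the edge and falls outside in another random draw. This holds for the TFIIS mock pool as control. With the TFIISmut mock pool as control more lists lay outside, some of them among these 17. For TFIISmut mock minus TFIIS induced, the median was 0.28 for cytosolic ribosomal proteins and -0.23 for jasmonate response. Leaving out organelle genes gave 60 genes higher and 112 lower; when the pools were also rescaled to a common sum, which shifts all genes, 43 were higher and 158 lower, 21.4% higher against 46.7%.

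**Figure D3:**
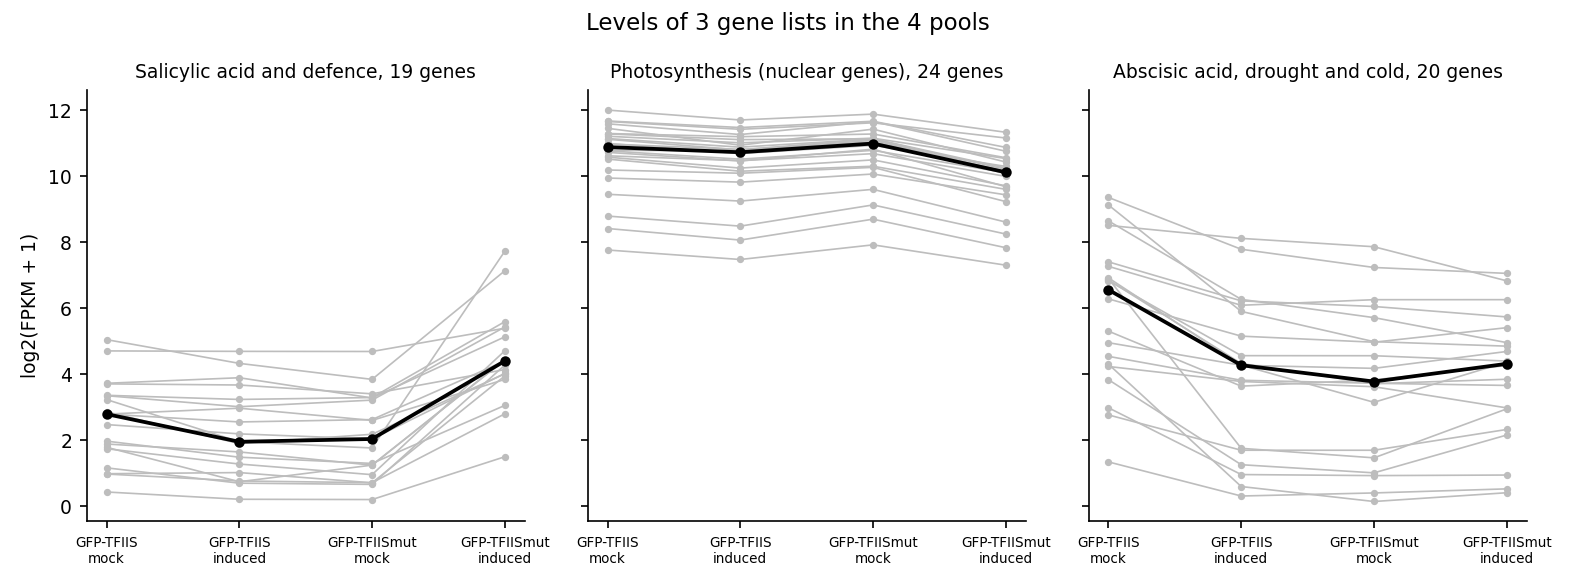
Levels, as log2(FPKM + 1), of the measured genes of 3 lists in the 4 pools; each grey line is a gene and the black line the list median, with 1 pooled value per gene and condition. The median of the salicylic acid list is 4.41 in TFIISmut induced and 2.80, 1.96 and 2.04 in TFIIS mock, TFIIS induced and TFIISmut mock; that of the abscisic acid list is 6.56 in TFIIS mock and 4.28, 3.78 and 4.32 in the others.

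The difference of the induction effects, TFIISmut minus TFIIS, asks which responses to induction are particular to a line. PR1 had the largest value, a log2 difference of 7.24, followed by EGC2 at 7.15, RAB18 at 6.63, CYP71A13 at 6.07 and DTXL2 at 5.94. The lowest were chloroplast rows, with the shared row of the transfer RNA genes TRNF and TRNL.1 at -9.13, TRNP at -5.88, PSBZ, a small subunit of photosystem II, at -5.79 and PSBN at -5.34, and the small nucleolar RNA gene SNOR30 at -5.32. By the rule of size, 975 genes were higher and 441 lower. Of the 24 lists, 11 lay above and 5 below: salicylic acid and defence genes had a median of 2.42, ethylene and early stress regulators 1.26, oxidative stress genes 1.03 and photosynthesis genes -0.56. The abscisic acid list, at 1.66, and RAB18 are among the higher here through the TFIIS mock pool. So is the glucosinolate list, at 0.47, which lay within the range of random lists in the TFIISmut line, at 0.03, and between the induced pools, at 0.01. The first rank of PR1 rests partly on that pool, since PR1 differed by -1.28 in the TFIIS line. EGC2 stood above PR1 in the TFIISmut line, at 6.30 against 5.96, and between the induced pools, at 6.40 against 5.77.

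Few genes passed the rule of size in both lines. Among 13792 genes eligible in both comparisons, 17 were higher in each line, where independent lists would share 2.53, and 3 were lower in each, against 1.42. Only 6 of the 17 are nuclear protein-coding genes, against 1.06 for independent lists, and TFIIS, the induced gene, is among them. With the TFIISmut mock pool as control for the TFIIS line, 17 of the 17 kept their sign and 13 passed the rule. The 3 lower genes kept their sign and 0 passed. In opposite directions, 16 were higher in the TFIISmut line and lower in the TFIIS line, against 2.88, and 15 the reverse, against 1.24. PR1 and RAB18 are of the first kind, and BT1 and SEN1 (AT4G35770) of the second. The first kind rests largely on the TFIIS mock pool: with the TFIISmut mock pool as control for the TFIIS line, 6 of the 16 kept their sign and 1, the camalexin gene CYP71A12, passed the rule. PR1 and RAB18 did not keep their sign. Of the 15 of the second kind, 15 kept their sign and 4 passed the rule, of which 3 are chloroplast rows and the other is SNOR30. Across the 13792 genes, which are not independent replicates, the induction effects had a Pearson correlation of -0.08 and a Spearman correlation of -0.06.

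For TFIISmut mock against TFIIS mock, the lines before induction, 35 genes were higher and 111 lower among 14113 eligible genes. The lower genes were again led by RAB18, with a log2 difference of -5.43, AT3G02480 at -5.32 and LTP4 at -4.45, and 15 of 20 measured abscisic acid and drought genes were 2-fold or more lower, with a list median of -1.76. RABA4A (AT5G65270; chromosome 5, 26083216 to 26084832), a small GTPase of membrane traffic, was higher in the TFIISmut line, at 58.7 FPKM against 9.94 FPKM. It was also higher after induction, at 64.9 against 10.6 FPKM. The chloroplast transfer RNA row TRNP was at 356 against 53.2 FPKM. Of the 24 lists, 5 lay above and 9 below, so pools of uninduced seedlings also differed by more than random lists; the robust SD of all differences was 0.18, against 0.39 for induction in the TFIISmut line and 0.18 in the TFIIS line.

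For TFIISmut induced against TFIIS induced, where each line had received estradiol, some of the same genes were highest: EGC2 had a log2 difference of 6.40, PR1 5.77, DTXL2 5.77 and CYP71A13 5.47. Salicylic acid and defence genes had a median of 2.11, with 15 of 19 members 2-fold or more higher, proteasome genes 0.64 and photosynthesis genes -0.54, with 27 of 27 members below 0. PSBA, at -4.30, and PSBZ, at -4.84, were among the lowest. In all, 780 genes were higher and 376 lower among 14619, and 9 lists lay above and 5 below. Leaving out the 20 most abundant genes gave 780 higher and 375 lower; when the pools were also rescaled to a common sum, 611 were higher and 563 lower, 52.0% higher against 67.5%.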

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

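No paired analysis was possible because the columns carry no replicate numbers and no test was made; the planned fits with other tests, a replicate block, estimated correlations, a filter on 3 libraries and left-out libraries could not be run for the same reason. The rules for what counts as eligible are the only guard against low values, since read depth is unknown. Totals of genes, higher and lower together, stayed within 1.5 times under quantile normalization, a common median and a pseudocount of 0.1. They also did so without organelle or the 20 most abundant genes, both with the other genes rescaled to a common sum. Among the planned settings, totals of lists were computed only under quantile normalization, a common median, no filter and without organelle genes. These cover induction in each line and the difference of the effects, and stayed within 1.5 times. The separate directions moved more: without organelle genes, 43 genes were higher in the TFIIS line against 98, and 23 between the mock pools against 35. Without the rescaling, a choice made after the data were seen, these were 60 and 30. Without organelle genes, the rescaling moved the median of all genes to -0.15 in TFIIS induced against mock, and without the 20 most abundant genes to -0.12 between the induced pools. With no filter, the counts were 367 in the TFIIS line, 248 between the mock pools, 44 shared in the same direction and 67 in opposite directions, as more genes of low level enter. A pseudocount of 0.1 enlarged the log2 differences of genes with a low value in a pool, without a change of sign. The following were chosen after the data were seen. A 4-fold rule gave 281 genes in the TFIISmut line, 75 in the TFIIS line, 417 for the difference of the effects, 37 between the mock pools and 312 between the induced pools, with 6 shared in the same direction and 3 in opposite directions. A minimum of 1 FPKM gave 51 in opposite directions, and nuclear protein-coding genes alone 8 in the same direction. Against the other line's mock pool, TFIIS differed by 2.00 in the TFIISmut line and 5.32 in the TFIIS line, and in the TFIIS line 125 genes passed the rule and 11 lists lay outside the range of random lists. There, 8 named genes changed sign: RAB18 to 0.29, AT3G02480 to 0.64, LTP4 to 0.25, AT1G52690 (LEA7) to 0.40, LTI65 to 0.45, AT3G03341 to 0.71, TSPO to 0.12 and LEA4-5 to 0.69. These follow from the high level of the genes in the TFIIS mock pool. Why it is high is not settled: a single library of that pool, examined below, could not be told apart from all 3.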

Other observations

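All patterns below were noticed in the data. The tests on abscisic acid, organelle and stress genes were chosen after their results were seen, except that on a single library of the TFIIS mock pool. The tests on gene length, on mitochondrial genes and on sugar starvation genes were written before their values were computed, on lists assembled after the data were seen.

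Genes of the camalexin pathway were listed because CYP71A13 and PAD3 had been seen among the largest differences. Of the 5 others, 3 were 2-fold or more higher in TFIISmut induced than in TFIISmut mock. The median log2 difference across the 5 was 1.48, and 1.07 against the TFIIS mock pool. The list was assembled after the data were seen, so these 5 genes are not an independent check. CYP71A12 was at 13.9 and 63.2 FPKM, GSTF6, a glutathione transferase, at 253 and 2368 FPKM, and CYP79B2, which makes the indole precursor, at 48.3 and 136 FPKM, while its homologue CYP79B3 was at 28.2 and 32.5 FPKM. Some transcripts were high in each induced line: AT1G15405, a noncoding RNA (chromosome 1, 5297875 to 5298166), was at 44.0 and 1287 FPKM in the TFIIS line and at 76.4 and 748 FPKM in the TFIISmut line. In the TFIIS line AT2G01021 was at 14286 and 117382 FPKM, the highest value of the table. Between the lines, 8 nuclear protein-coding genes differed 2-fold in the same direction before and after induction, among them CORI3 (83.6 against 27.3 FPKM in mock) and RCI2B (42.1 against 19.3 FPKM), both lower in the TFIISmut line.

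AOX1A, UPOX and UGT74E2, high in TFIISmut induced, are known to respond to impaired mitochondria, and a hypothesis is that a wider group of such genes was higher. In a list without these 3 genes, 9 of 9 members were 2-fold or more higher, with a median of 2.91 against -0.27 to 0.33 for random lists. NDB4, an alternative NADH dehydrogenase, was at 0.939 and 32.4 FPKM, OM66, an outer membrane protein, at 3.48 and 53.4 FPKM, and ANAC013, a transcription factor of this response, at 7.72 and 44.2 FPKM. In the TFIIS line the median of the 7 measured members was -0.33. The values may reflect a retrograde response of mitochondria, but several of these genes also respond to other stresses, and DTX3 and DTXL2 are related transporter genes whose reads could be shared.

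ASN1, an asparagine synthetase, was at 23.2 and 8.10 FPKM in the TFIISmut line and at 9.50 and 39.2 FPKM in the TFIIS line, and SEN1 (AT4G35770) differed in the same ways; both are known to be high in dark or sugar-starved leaves. A wider list of sugar starvation genes without these had a median of -0.56 in the TFIISmut line, with 12 of 15 members below 0, and of 0.62 in the TFIIS line, with 14 of 15 above 0. DIN10 was at 246 and 114 FPKM in the former and at 167 and 321 FPKM in the latter. Against the TFIISmut mock pool the median in TFIIS induced was 0.40. Against the TFIIS mock pool that in TFIISmut induced was -0.14, with 11 of 15 below 0, so much of the lowering in the TFIISmut line rests on its own mock pool, which stood 0.26 above the TFIIS mock pool. The sugar status of the seedlings may have differed between the pools. The time of harvest or the light could do the same, and neither was tested. The circadian clock list, not used as a test of this, lay above between the mock pools, at 0.25. It lay below in the TFIISmut line, at -0.31, and within the range of random lists in the TFIIS line, at 0.10.

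Abscisic acid and drought genes were lower after induction in the TFIIS line. A lowering from a level shared by uninduced seedlings is argued against by the mock pools, which differed by a list median of -1.76. The TFIIS mock pool standing apart is in line with a median of -0.18 between TFIISmut mock and TFIIS induced. A single stressed library in that pool could not be told apart from all 3: 15 genes lay below all other pools by more than log2(2/3), against 42, 31 and 672 in the other pools, but this bound holds only if the pooled value is a plain mean, which is not stated. A baseline particular to the TFIIS line, which induction then lowered, stays open and was not tested.

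Organelle transcripts were higher in TFIIS induced. Carry-over of RNA without a poly(A) tail and a change of transcription in the organelles cannot be told apart by nuclear small RNA rows. These rows, the only ones used for this question, had a median of 0.31, between the bounds set for either. Of 42 rows, 10 were 2-fold higher and 2 lower, while between the mock pools 8 of 45 were higher and 7 lower. Whether other nuclear RNA without a poly(A) tail was higher too was not examined. Library totals and poly(A) selection per library were not analysed here.

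Stress genes were higher and photosynthesis genes lower in TFIISmut induced. For the stress genes, estradiol by itself is argued against by the salicylic acid list in the TFIIS line, with a median of -0.28 after the same treatment and 0.19 against the TFIISmut mock pool; photosynthesis genes were lower there too, at -0.25, so a part of their lowering by estradiol stays open. For the stress genes, an unusual TFIISmut mock pool is argued against by the median of 2.11 when TFIIS induced serves as the control, and a larger share of root RNA by root markers at -0.51. A single library carrying the lower photosynthesis genes cannot be told apart from all 3: their median of -0.83 lies beyond the -0.58 that a lost library would give in a plain mean, but how libraries were combined is not stated. An effect of the mutated protein may explain the pattern and stays a hypothesis, since the line and the protein are confounded and the transgenes differed in level.

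Because TFIIS acts in transcript elongation, longer genes might be lower when GFP-TFIISmut is expressed. Across 13534 nuclear protein-coding genes, which are not independent, gene length and the difference in the TFIISmut line had a Spearman correlation of -0.20, against 0.17 in the TFIIS line and -0.04 between the mock pools. Strongly differing short genes did not make the trend, since it was -0.19 across the 12574 genes under 2-fold apart. Loss of long RNA in the libraries could also give it: the partial rank correlation with spliced length, given intron length, was -0.16, and that with intron length, given spliced length, -0.07. The trend follows the length of the mature RNA more than that of introns, so a technical origin stays open beside an effect on elongation. The sign was opposite in the TFIIS line, where the partial correlation was 0.14 with spliced length and 0.04 with intron length. There too the trend followed the length of the mature RNA more. No replicate values exist here to say how much such a trend varies between libraries.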
